A study of Mus musculus with 16 samples.

How the data were processed

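Total RNA of livers from 16 C57BL/6J mice was sequenced, 8 females and 8 males, with 4 animals in each of 4 groups. Per the labels, the offspring were exposed to bisphenol A (BPA) in utero, and the livers were taken at 24 weeks and frozen. RNA was extracted with a Qiagen miRNeasy kit, and libraries were made with a total RNA kit and Ribo-Zero Gold, which removes ribosomal RNA. The dose, the litters, the sequencing runs and the strand setting of the counting are not given in the sources used here.

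The deposited table held 1 column of estimated counts per sample for 24062 gene symbols. The values were already whole numbers, not scaled to library size, and they were used as they stood. Low values piled up at 7, 13, 20 and 26, with 3622, 1846, 1165 and 998 values at these steps, as counts computed from coverage do. Per the submitters' processing notes, FastQC, HISAT, StringTie and DESeq2 were used with the GRCm38 (mm10) build, with no versions and no further detail of each tool's part.

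Each symbol was matched to the GENCODE M21 annotation of GRCm38, 22750 by the symbol itself and 916 by a synonym, which left 396 unmatched. The match gave positions, exon lengths, GC content, overlap with exons of other genes, and the share of each gene's 31-mers that also occurred in another gene. A gene with at least 20% of its 31-mers shared or of its exon length overlapped was taken as one whose counts other genes could have contributed to.

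Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with the 4 groups, which left 13482 genes, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per group and a robust prior was fitted to all 16 libraries. The contrasts were BPA against control in females, BPA against control in males, the mean of both, the male minus the female BPA effect, and male minus female in controls and in exposed animals. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and all tests were two-sided. Changes are log2 fold changes with standard errors (SE) from the model, and levels are CPM, counts scaled by effective library size, with the standard deviation (SD) over 4 animals. A change said to be seen in 4 of 4 libraries had that many exposed libraries on its side of the control mean, unless stated. Between the sexes, male libraries were set against the female mean. Genes were named for their difference in means, so these numbers are no independent support. Where all libraries of a group stood at 0, the fold was bounded by 3 counts over the group, which covers counting error only. This bound lies below the first step of 7 at which the estimated counts piled up. Folds given as at least a value are therefore nominal and could be smaller.

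For 38 gene lists, camera in limma 3.58.1 tested whether the listed genes moved relative to the other genes. It used log2 CPM with a prior count of 2 and a preset correlation of 0.01, and was run on the 35 lists with at least 3 tested genes. Camera with an estimated correlation and the fry test were run beside it. Values by fry are of its test of a common direction unless stated. Its test of changes in either direction also passed for lists that these tests did not call. The mitochondrially encoded list had 0 of its 15 genes in the table, and the pancreas and muscle lists had 1 tested gene each, so these lists were not tested.

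The gene lists and the rule for the genes named were written before the data were examined. By this rule, among genes that passed and had a mean of at least 1 CPM, the genes named were the 10 with the largest rise and the 10 with the largest fall in each sex, and 5 in each direction for the other contrasts. Where fewer than 5 passed in a direction, the genes of lowest p were added. Up to 4 genes of lowest p were taken from each list described, with the BPA-binding receptors and the sex-linked genes named in every case. Of the genes this rule selected, 2 are not reported here. All other choices of test, scaling and filter were also made at that point unless stated.

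The gene and list tests, but not the splits of the libraries, were tried on simulated data with known changes in 50 genes per size. The simulated counts used gene means, library sizes and the spread that edgeR estimated from the same libraries. Of genes changed 2-fold, 80% were recovered in females, 82% in males, 94% on the average of both sexes and 52% for the difference between the sexes. At 1.5-fold the shares were 46%, 48%, 66% and 12%. Simulated genes varied independently and had no sex difference, and all changed genes had a mean of at least 1 CPM. Far fewer genes were changed than were called in the data, so these shares need not hold for the data.

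Alternatives covered other size factors, other filters, DESeq2 1.42.0, limma-voom with sample quality weights, a prior that was not robust, fits on the compared groups alone and leaving out each library in turn. Thinning to equal depth, a correction for exon length and GC content, and leaving out certain genes or 2 libraries at the ends of principal components 3 and 4 (male BPA 12 and female control 17, but not male control 7 at the other end of component 4) were added after the data were seen. Genes were also counted in splits of the same libraries, all 35 of 8 libraries or 100 of both sexes, the real split included in each number. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No litter or batch was given, so p-values measure the spread between these animals, and handling shared by all exposed animals cannot be told apart from the exposure.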

Results

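Liver RNA was measured in adult mice exposed to BPA in utero, with corn oil, the control of each sex, as background. BPA is a monomer of polycarbonate plastics that binds estrogen receptors. The groups were female control, female BPA, male control and male BPA, each of 4 animals. Total counts per library lay between 19.4 and 32.2 M counts (M, 1e6). They averaged 30.7 ± 1.7 M in exposed females, 22.8 ± 3.7 M in control females, 27.1 ± 1.6 M in exposed males and 22.9 ± 1.2 M in control males (SD, n = 4 each). Exposed libraries were deeper than controls in both sexes (28.9 ± 2.4 against 22.9 ± 2.5 M, n = 8 each, exact permutation p = 0.000622) and had more genes with a count (15202 ± 324 against 14705 ± 265, exact permutation p = 0.00544).

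Sex-linked genes matched the labelled sexes. Xist, the RNA that silences one X chromosome in females, had 11310 to 21080 counts in females and 15 to 37 in males. The Y-linked helicase gene Ddx3y had 3100 to 4299 counts in males and at most 20 in a female library. Albumin, the main hepatocyte transcript, took 10.02 ± 0.14% of the counts in exposed and 10.11 ± 0.52% in control females, and 7.6 ± 1.08% and 8.04 ± 0.57% in exposed and control males. The coefficient of biological variation was 0.21, and Spearman correlations across genes between libraries of a group lay between 0.978 and 0.991. Principal component 1, with 34.4% of the variance, separated the sexes, and principal component 2, with 13.5%, separated exposed from control animals in both sexes. Male BPA 12 stood apart on component 3 (7.1%, at −50.27 with the others between −18.21 and 23.01) and had 6.03% albumin counts (7.85 to 8.5% in the other exposed males), and female control 17 and male control 7 lay at the 2 ends of component 4 (6.3%, at −33.9 and 29.65, with the others between −20.96 and 16.11).

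**Figure D1:**
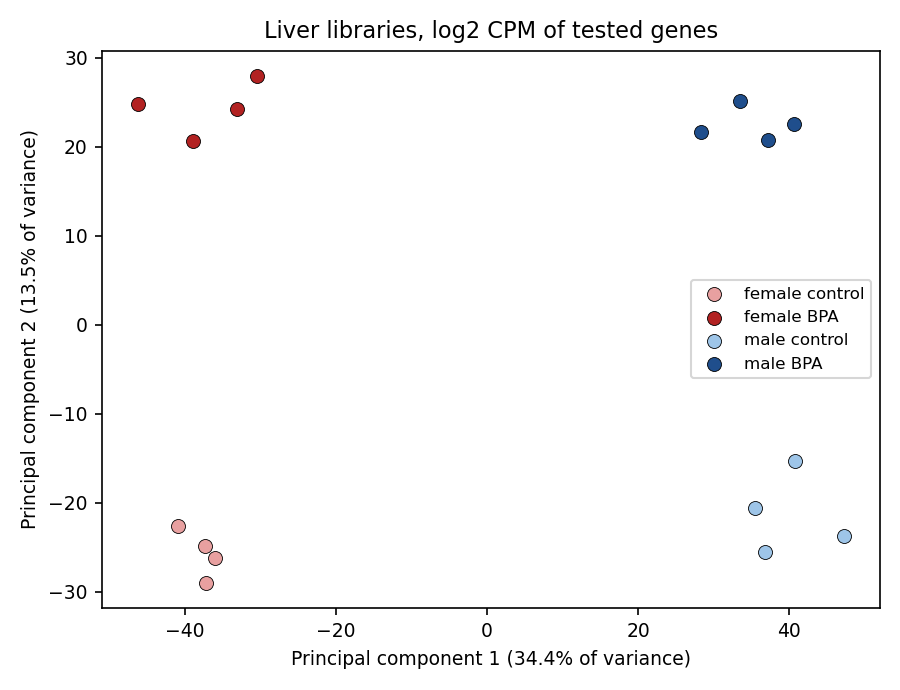
Each point is a liver library placed by the first principal components of log2 CPM, with the percent of variance on each axis and 4 libraries per group. Sexes part along component 1 (34.4%) and exposed from control animals along component 2 (13.5%).

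Which liver genes differed between exposed and control females was asked first. Of all tested genes, 20.6% passed in females and 15.1% in males, which is the background for the counts within each list. Nuclear-encoded genes of the respiratory chain rose in exposed females: of 32 tested, 22 rose, 2 fell and 8 did not pass, with 22 and 3 when adjusted over the list alone. Ndufa4 went from 91.0 ± 3.44 to 153 ± 8.87 CPM (SD, n = 4) and Cox5a from 44.6 ± 1.55 to 77.6 ± 6.39 CPM, both encoding subunits of cytochrome c oxidase. Their log2 changes were 0.75 ± 0.06 (SE, adjusted p = 3.17e-06) and 0.80 ± 0.07 (adjusted p = 7.62e-06), each seen in 4 of 4 exposed libraries. Ndufa2, of complex I, rose by 1.05 ± 0.11 and Cox7c, another oxidase subunit with 29.4% of its sequence shared with other genes, by 0.72 ± 0.07, both in 4 of 4 libraries. Camera called the list higher (median log2 change 0.31, adjusted p = 3.29e-08), with adjusted p = 0.987 with an estimated correlation. The fry test of a common direction gave adjusted p = 0.00531.

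Of 26 amino acid and one-carbon genes, 9 rose, 1 fell and 16 did not pass in females, against 10 and 1 when adjusted over the list alone. Gnmt, which methylates glycine with S-adenosylmethionine, rose from 651 ± 110 to 1154 ± 185 CPM (log2 change 0.83 ± 0.12, adjusted p = 2.85e-04). Gls2, the liver glutaminase, rose by 1.27 ± 0.25 and the urea cycle gene Otc by 0.52 ± 0.11, whereas Bhmt2, a homocysteine methyltransferase gene, fell by 0.41 ± 0.10 on the log2 scale. Of 34 xenobiotic metabolism genes, 11 rose, 1 fell and 22 did not pass, against 14 and 2 when adjusted over the list alone. The carboxylesterase gene Ces2a rose from 130 ± 16.0 to 230 ± 32.2 CPM and Cyp3a25, a cytochrome P450 gene, from 548 ± 93.9 to 906 ± 202 CPM (adjusted p = 1.20e-04 and 0.00404). The glutathione transferase genes Gsta2 and Gsta1 rose by 1.43 ± 0.30 and 1.73 ± 0.44. These 4 genes share 37.6%, 47.2%, 76.2% and 92.3% of their sequence with other genes, so their values are uncertain. Each change named here was seen in 4 of 4 exposed libraries. Camera called both lists higher (adjusted p = 0.00897 each), with adjusted p = 0.987 with an estimated correlation and 0.0571 and 0.0861 by fry.

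Fatty acid oxidation genes included 7 of 31 that fell in females, none that rose and 24 that did not pass, with the same 7 and 0 when adjusted over the list alone. Acadl, the long-chain acyl-CoA dehydrogenase gene, fell from 443 ± 34.3 to 267 ± 23.4 CPM (adjusted p = 4.18e-05), and Fabp1, the liver fatty acid carrier gene, from 6320 ± 1060 to 3944 ± 726 CPM (adjusted p = 0.00313). Vnn1 and Cyp4a32, targets of PPAR alpha, fell by 0.70 ± 0.18 and 0.60 ± 0.16 on the log2 scale, Cyp4a32 with 65% shared sequence. Of 22 NRF2 targets, 8 rose and 14 did not pass, and adjusted over the list alone 9 rose and 2 fell. The quinone reductase gene Nqo1 rose by 0.56 ± 0.14 and the ferritin gene Ftl1 by 0.51 ± 0.11, the latter with 84.6% shared sequence. Ribosomal protein genes moved both ways, with 13 of 34 up and 6 down by either adjustment. Rps14 rose by 0.97 ± 0.10, Rpl18 by 0.67 ± 0.08 and Rps18 by 0.62 ± 0.08, and Rpl23 fell by 0.75 ± 0.09 on the log2 scale. All these changes were seen in 4 of 4 libraries, and camera called none of these 3 lists (adjusted p = 0.0771 each). Fry's test of changes in either direction passed for each (adjusted p = 1.81e-05, 5.87e-06 and 6.49e-09). With 1 library left out, fatty acid oxidation was called lower without female BPA 14, 8 or 9 (adjusted p = 0.0408, 0.033 and 0.0379) and ribosomal proteins higher without female control 4 (0.00605).

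Of the receptors named for binding BPA, Esr1 and Esrrg did not pass in either sex. Esr1, the main hepatic estrogen receptor (chromosome 10, 4611593 to 5005614, GRCm38), measured 0.17 ± 0.15 in females (adjusted p = 0.443, above the control mean in 3 of 4 libraries) and 0.11 ± 0.15 in males (adjusted p = 0.688, 2 of 4), with 0.083 without female control 4 and 0.038 without male BPA 12 as the lowest with 1 library left out. Esrrg, the estrogen-related receptor with high affinity for BPA (chromosome 1, 187608791 to 188214885), measured −0.52 ± 0.37 in females and −0.52 ± 0.39 in males (adjusted p = 0.357 and 0.425, below the control mean in 4 of 4 libraries of each sex), but −0.205 without female BPA 1 and −0.27 without male BPA 12. Esr2, with 6 counts in total, and Gper1, with 49 counts, were too low to test. On the wider list of estrogen and xenobiotic nuclear receptors, 2 of 14 tested genes rose in females by either adjustment and none in males. These were Esrra, a regulator of mitochondrial genes (0.52 ± 0.12, adjusted p = 0.00806), and Ahr, the dioxin receptor (0.35 ± 0.10, adjusted p = 0.0264), both in 4 of 4 libraries. Rxra and Thrb measured 0.64 ± 0.25 and 0.61 ± 0.25 without passing (adjusted p = 0.0895 and 0.104). The call of Ahr ended in 4 of 8 fits with 1 library left out (highest adjusted p = 0.0760, without female BPA 14), and Rxra passed without female control 17 (adjusted p = 0.0182).

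In females 1 of 21 imprinted genes rose and 2 fell, and in males 3 fell, by either adjustment. With 20.6% of all tested genes passing in females and 15.1% in males, these counts do not single out imprinted genes. Slc22a18 rose in females (0.78 ± 0.12, adjusted p = 3.62e-04, 4 of 4 libraries). Kcnq1ot1, the RNA that silences its imprinted cluster, fell by 0.62 ± 0.15 in females and by 0.64 ± 0.15 in males on the log2 scale (adjusted p = 0.00907 and 0.0107, 4 of 4 libraries each). Airn, the RNA that silences Igf2r, fell by 1.16 ± 0.37 in females. The growth inhibitor gene Cdkn1c and the splicing factor gene Zrsr1 fell by 0.79 ± 0.18 and 0.48 ± 0.14 in males, again in 4 of 4 libraries, and Cdkn1c measured −0.40 ± 0.17 in females (adjusted p = 0.107). Sgce measured 0.58 ± 0.23 in males (adjusted p = 0.111). Camera did not call the list in females, where the median of −0.10 and the mean of 0.02 differed in sign (adjusted p = 0.683), nor in males (adjusted p = 0.236). The calls of Airn and Zrsr1 each ended in 6 of 8 fits with 1 library left out (highest adjusted p = 0.0952 without female control 1 and 0.124 without male BPA 15).

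Among single genes with a mean of at least 1 CPM, the largest rises in females were of Rslcan18, a zinc finger gene, by 3.93 ± 0.95 (adjusted p = 0.00987, 4 of 4 libraries), and Jund, an AP-1 transcription factor gene, by 3.69 ± 0.66 (adjusted p = 0.00169, 4 of 4). For Rslcan18 only 3 of 4 exposed libraries lay above all controls (0.768 to 10 against 0 to 0.813 CPM). Jund (chromosome 8, 70698949 to 70700616) went from 3.81 ± 0.866 to 49.1 ± 5.97 CPM, but 52.6% of its exons overlap Gm11175, and control males ranged from 2.41 to 72.7 CPM. Gm20594, an uncharacterised gene (chromosome 6, 79817916 to 79818364), rose 11.2-fold from 1.28 ± 0.175 to 14.4 ± 2.92 CPM (3.48 ± 0.22, adjusted p = 6.62e-07). The inducible Hsp70 genes Hspa1b and Hspa1a rose by 2.18 ± 0.60 and 2.03 ± 0.59, with 67.6% and 65.5% shared sequence. For Hspa1b and Hspa1a, control males spanned 24 to 147 and 16.1 to 93.9 CPM, against 36.8 to 91.1 and 22 to 52.3 in exposed females. Scarna10, a guide RNA for modification of spliceosomal RNA, rose by 2.11 ± 0.29, with 86.5% overlap with Gm28967. Further rises were of Sco2, a copper chaperone gene of cytochrome c oxidase (2.63 ± 0.83, 68.3% overlap with Tymp), the zinc finger gene Zfp281 (2.51 ± 0.80), the ribosome processing gene Utp14b (2.14 ± 0.70) and Fam134c (2.11 ± 0.52). Control males ranged from 11.6 to 14.8 CPM for Utp14b and 14.9 to 68.3 for Fam134c, against 10.4 to 14 and 27.6 to 76.6 in exposed females. The last 7 genes named, from Hspa1b to Fam134c, had adjusted p between 1.31e-04 and 0.0458, and each rise was seen in 4 of 4 libraries.

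Among genes with a mean of at least 1 CPM, the largest fall in females was of the adult beta globin gene Hbb-bt (chromosome 7, 103812524 to 103813996), from 22 ± 10.3 to 0.123 ± 0.246 CPM (−7.43 ± 0.99, adjusted p = 2.10e-04), a gene with 59.3% shared sequence. Mt1, the metal-binding metallothionein gene (chromosome 8, 94179082 to 94180327), fell from 282 ± 66.7 to 62.5 ± 19.5 CPM (−2.18 ± 0.46, adjusted p = 0.00506). The orphan nuclear receptor genes Nr4a1 and Nr4a2 fell by 3.20 ± 0.99 and 1.64 ± 0.45 on the log2 scale, but no exposed library lay below all controls for Nr4a1. The pseudogene Gm12669 fell by 2.98 ± 0.59, with 85.7% shared sequence, and Rsc1a1 by 2.04 ± 0.63, a gene that lies wholly within Ddi2. Smaller falls were of the sphingomyelinase gene Smpd3 (−1.66 ± 0.51), the RNA exosome gene Mphosph6 (−1.49 ± 0.23), Kbtbd12 (−1.47 ± 0.27) and Zfp13 (−1.43 ± 0.34). All 10 fell below the control mean in 4 of 4 exposed libraries.

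Across all genes, edgeR called 1366 up and 1407 down in females, 20.6% of the 13482 tested, with a median absolute log2 change of 0.48, and 159 rises and 68 falls of at least 2-fold. Which direction had more genes turned with the setting, for example to 1421 up and 1391 down with upper quartile scaling and 1386 and 1123 without the expression filter. Leaving out 1 library ended some calls: the highest adjusted p was 0.0726 for Hspa1a, 0.0601 for Hspa1b and 0.0923 for Zfp281 without female control 18. Without female control 4 it was 0.0615 for Nr4a2, 0.100 for Sco2 and 0.108 for Utp14b, without female control 1 it was 0.108 for Nr4a1, and without female control 17 it was 0.0995 for Rsc1a1 and 0.106 for Smpd3. Of the 8 such fits, 7 ended the call of Zfp281 and of Utp14b, 6 that of Nr4a1, Sco2 and Rsc1a1, 5 that of Hspa1a and Smpd3, 4 that of Hspa1b and 2 that of Nr4a2. The rise of Utp14b was 4.42 without female control 1, and Hbb-bt was at 0 in every exposed female but BPA 1. Among the named genes that did not pass with limma-voom were Rslcan18 and Nr4a1 (adjusted p = 0.0858 and 0.332), and among those that did not in an edgeR fit of females alone were Zfp281, Utp14b and Nr4a1 (0.0950, 0.165 and 0.131). Without the expression filter these 3 did not pass either (0.0550, 0.0635 and 0.0527).

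**Figure D2:**
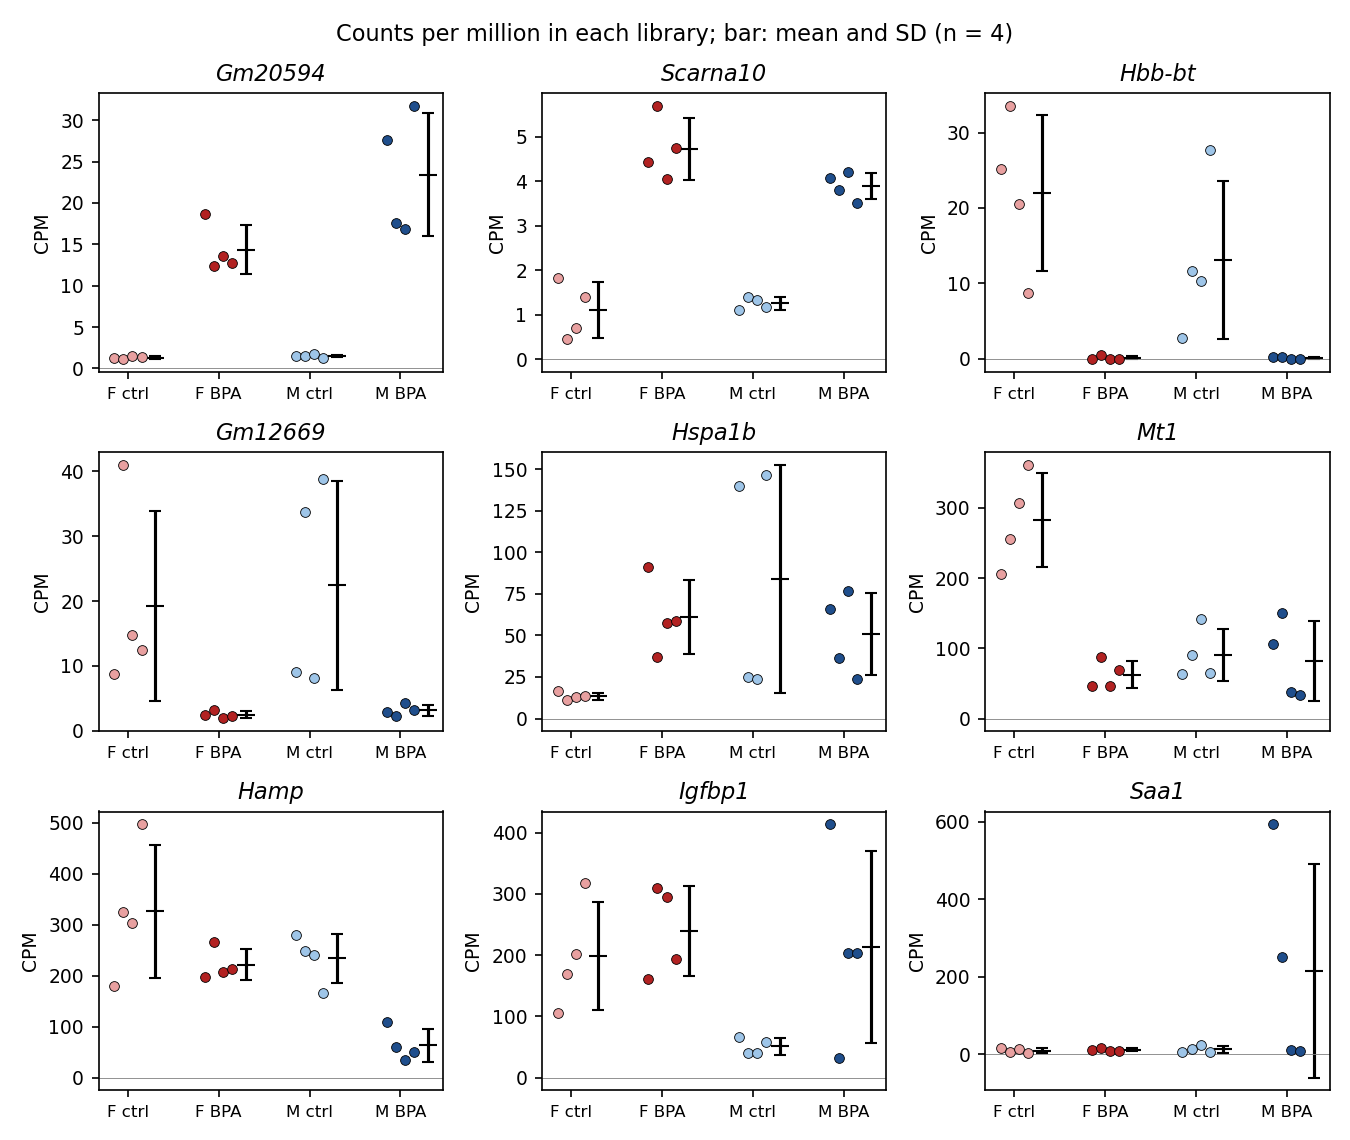
CPM of 9 genes in each library, with the mean and SD of 4 libraries per group beside the points (F, female; M, male; ctrl, control). Gm20594 rose and Hbb-bt fell in both sexes, and the rise of Saa1 in exposed males rested on 2 of 4 libraries.

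The same question in males gave acute phase and heat shock genes among the changes. Of 24 acute phase genes, 4 rose, 1 fell and 19 did not pass, with 5 and 1 when adjusted over the list alone. Hamp, which encodes the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), fell from 234 ± 48.5 to 63.3 ± 32.5 CPM (SD, n = 4; log2 change −1.89 ± 0.34, adjusted p = 0.00257, 4 of 4 libraries), with 35.5% shared sequence. The serum amyloid genes Saa2 and Saa1 rose by 5.14 ± 1.23 and 4.08 ± 1.15 (adjusted p = 0.0144 and 0.0312), but for each only 2 of 4 exposed libraries lay above all controls, and exposed values spanned 3.94 to 306 and 9.51 to 594 CPM. Apcs, the serum amyloid P gene, rose from 25.2 ± 3.85 to 53.6 ± 26.5 CPM (1.09 ± 0.28, adjusted p = 0.0188, 4 of 4). Of 14 heat shock genes, 4 fell and 10 did not pass, by either adjustment. The cochaperone gene Bag3 fell by 0.89 ± 0.23, Hsp90ab1 by 0.48 ± 0.15, Hspa4 by 0.33 ± 0.09 and the mitochondrial chaperonin gene Hspd1 by 0.31 ± 0.10 on the log2 scale (adjusted p = 0.0150, 0.0462, 0.0183 and 0.0400, each in 4 of 4 libraries). Camera called neither list (adjusted p = 0.117 and 0.0946). With 1 library left out, heat shock was called lower without male BPA 12, male BPA 3, male control 2 or male control 3 (adjusted p = 0.00489, 0.0104, 0.00501 and 0.000969), and the acute phase higher without male BPA 3 or male BPA 4 (0.0057 and 0.00124).

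Of 32 respiratory chain genes, 11 rose, 3 fell and 18 did not pass in males, against 15 and 5 when adjusted over the list alone. Cox5a rose from 56.1 ± 2.97 to 88.5 ± 6.45 CPM (0.66 ± 0.07, adjusted p = 5.26e-05), Ndufa4 by 0.52 ± 0.06 and Cox7c by 0.53 ± 0.07, whereas Ndufa1, of complex I, fell from 60.9 ± 3.05 to 38.4 ± 4.01 CPM (−0.66 ± 0.08, adjusted p = 9.79e-05). Camera called the list higher (median 0.14, adjusted p = 0.00479), with adjusted p = 0.972 with an estimated correlation and 0.262 by fry. Of 34 xenobiotic genes, 2 rose, 4 fell and 28 did not pass, by either adjustment, and the list was not called (adjusted p = 0.236). The sulfotransferase gene Sult1a1 fell by 0.43 ± 0.09, the epoxide hydrolase gene Ephx1 by 0.41 ± 0.11 and Cyp2e1, the ethanol-oxidising P450 gene, from 11860 ± 612 to 7984 ± 441 CPM, whereas the efflux pump gene Abcb1a rose by 0.62 ± 0.16. Of 23 lipoprotein genes, 2 rose and 4 fell, or 3 and 5 when adjusted over the list alone. Apom, of high-density lipoprotein, rose by 0.61 ± 0.08, and Apoa2 and Apoe fell by 0.59 ± 0.11 and 0.37 ± 0.07 on the log2 scale. These changes held in 4 of 4 libraries each, and camera did not call the lipoprotein list (adjusted p = 0.898).

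Among single genes in males, Gm20594 rose 15.3-fold from 1.52 ± 0.161 to 23.4 ± 7.39 CPM (3.94 ± 0.22, adjusted p = 1.07e-07, 4 of 4 libraries). Tcf20, a transcriptional coregulator gene, rose from 15.4 ± 1.64 to 116 ± 8.38 CPM, Ly6e, a membrane-anchored protein gene, from 8.73 ± 3.56 to 77.4 ± 8.18 CPM, and Stx16, a Golgi syntaxin gene, from 6.37 ± 0.841 to 22.2 ± 1.81 CPM (adjusted p = 0.00286, 0.0116 and 0.00630, 4 of 4 each), but control females ranged from 14.7 to 116, 7.32 to 114 and 4.8 to 23.1 CPM for these 3 genes. Rises also passed for the carnitine transporter gene Slc22a21 (4.49 ± 1.10, 33.2% shared sequence), the ephrin receptor gene Ephb6 (3.95 ± 0.82) and Zfp281 (2.77 ± 0.81), with adjusted p = 0.0138, 0.00438 and 0.0353 and 4 of 4 libraries each. Igfbp1, which encodes a binding protein of insulin-like growth factors (chromosome 11, 7197782 to 7202546), rose from 50.7 ± 13.6 to 213 ± 156 CPM (2.07 ± 0.58, adjusted p = 0.0283, 3 of 4 libraries). Kctd12, a subunit gene of GABA-B receptors (chromosome 14, 102976581 to 102982637), was at 21.9 ± 1.90 CPM in controls and at 0 in all 4 exposed libraries, at least 754-fold lower (adjusted p = 0.0297), with 62.8% of its exons overlapping Gm26778. Hbb-bt fell from 13.1 ± 10.5 to 0.0819 ± 0.0953 CPM (−7.31 ± 1.10, adjusted p = 8.32e-04) and Gm12669 by 2.83 ± 0.59.

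Several of the other falls in males lay in genes that overlap a neighbour. These were the antisense transcript Phtf1os (−2.44 ± 0.77, 51.9% overlap with Rsbn1), Tmem198b (−2.41 ± 0.64, 23.5% with Mmp19), Rsc1a1 (−2.10 ± 0.64), Iqcg (−1.54 ± 0.42, 48.1% with Lrch3), the antisense transcript 1700018L02Rik (−1.41 ± 0.40, 11.4% with Ak3) and the helicase gene Recql (−1.41 ± 0.24, 37.7% with Pyroxd1). Male controls spanned 0.581 to 4.77 CPM for Phtf1os, 1.74 to 19 for Tmem198b and 1.16 to 6.44 for Iqcg. All fell below the control mean in 4 of 4 libraries, with adjusted p between 0.00137 and 0.0455. The strand that was counted is not stated, so reads of either neighbour could have been included. Of 5 tested sex chromosome genes, 2 fell in males by either adjustment and none passed in females. The Y-linked translation factor gene Eif2s3y fell from 73.0 ± 3.82 to 50.2 ± 2.83 CPM (−0.54 ± 0.07, adjusted p = 0.00138, 4 of 4 libraries below all controls). Xist, at 1.34 ± 0.406 and 0.721 ± 0.100 CPM in control and exposed males, fell by 0.90 ± 0.26 on the log2 scale (adjusted p = 0.0311, 4 of 4), a call that ended in 7 of 8 fits with 1 library left out (highest adjusted p = 0.0992, without male control 3) and with limma-voom (adjusted p = 0.375). Uty and Kdm5d measured −0.07 ± 0.09 and −0.17 ± 0.27 (adjusted p = 0.663 and 0.733). Camera did not call the list in males (adjusted p = 0.162), whereas fry did (adjusted p = 0.0363).

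Across all genes, edgeR called 860 up and 1181 down in males, 15.1% of those tested, with a median absolute log2 change of 0.45, and 97 rises and 35 falls of at least 2-fold. The excess of falls was not stable: the split was 1049 and 1054 with upper quartile scaling, and rises outnumbered falls without male BPA 12 (958 and 883), male BPA 15 (898 and 726), male BPA 3 (768 and 699), male control 2 (818 and 758), male control 3 (840 and 804) or male control 7 (900 and 734). Calls that ended with 1 library left out had their highest adjusted p without male control 7 for Bag3 (0.0594), Ephx1 (0.0812), Hsp90ab1 (0.172), Hspa4 (0.100) and Hspd1 (0.173). It came without male control 10 for Apcs (0.0542), Iqcg (0.0917), Tmem198b (0.0619) and Zfp281 (0.0864), without male control 3 for Phtf1os (0.131) and Rsc1a1 (0.117), and without male BPA 12 for Igfbp1 (0.0759) and Saa1 (0.0871). It came without male BPA 15 for 1700018L02Rik (0.0810), and without male BPA 3 for Cyp2e1 (0.0888) and Kctd12 (0.0616), which did not pass in any of the 8 fits with 1 library left out (lowest adjusted p = 0.0519). Of these 8 fits, 7 ended the call of Hspd1 and of Zfp281, 6 that of Cyp2e1, Phtf1os and Rsc1a1, 5 that of Hsp90ab1, Igfbp1, Iqcg and Saa1, 4 that of Tmem198b and 1700018L02Rik, 3 that of Bag3, Ephx1 and Hspa4 and 1 that of Apcs. Without male control 7 the falls of Hspa4 and Ephx1 measured −0.215 and −0.27, and Ephb6 was at 0 in every control male but control 10 (0.0894 CPM). Among the named genes that did not pass with limma-voom were Saa2 (adjusted p = 0.356), Saa1 (0.417), Slc22a21 (0.242), Kctd12 (0.0702) and Hbb-bt (0.0564), and among those that did not in an edgeR fit of males alone were Saa2, Saa1 and Igfbp1 (0.0926, 0.136 and 0.0932).

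**Figure D3:**
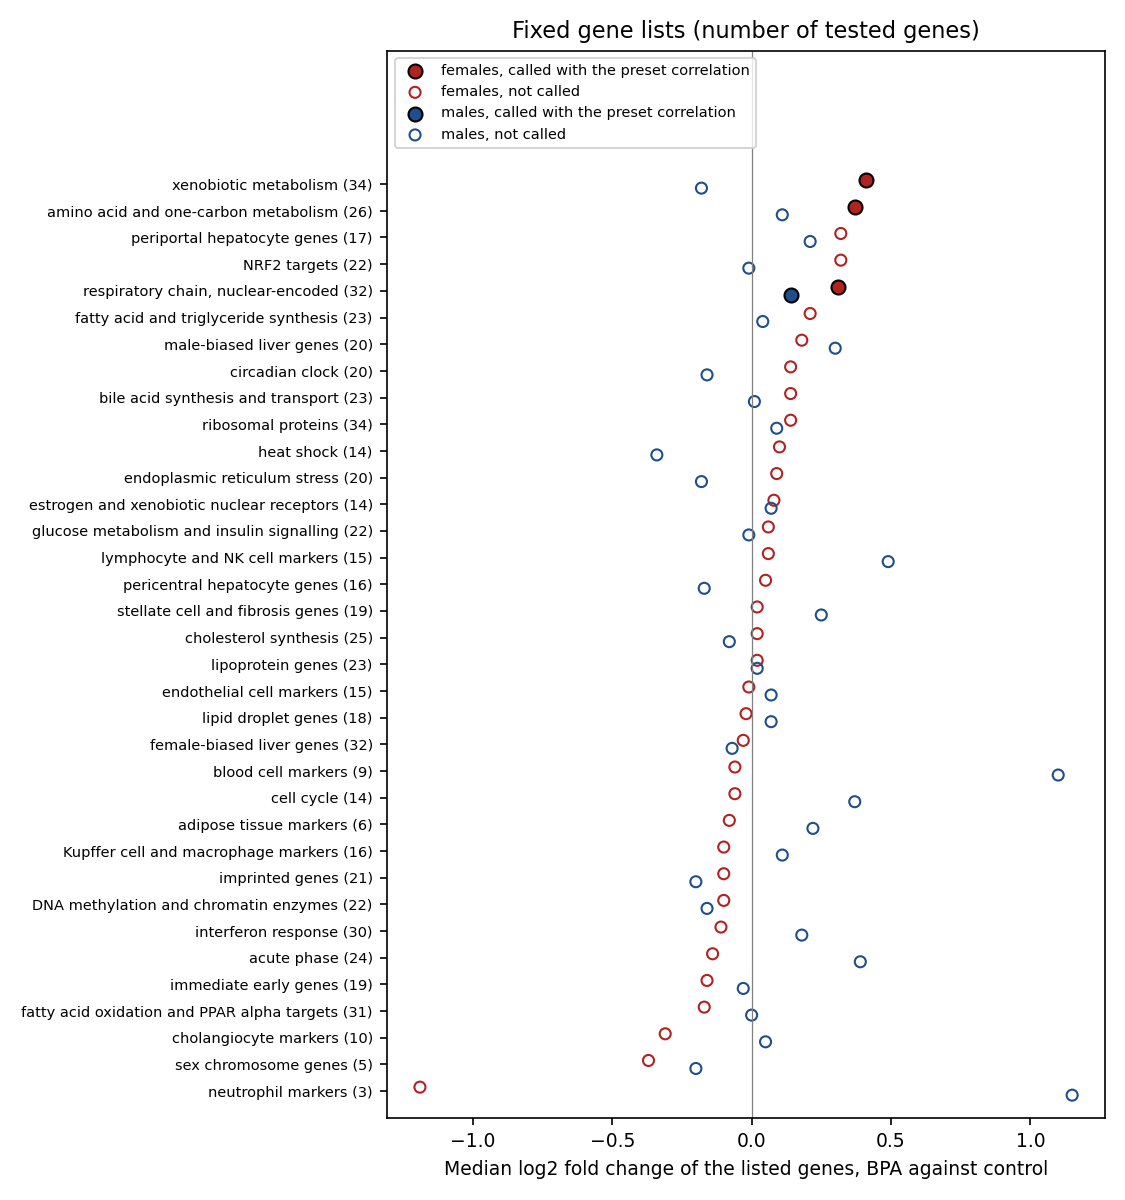
Median log2 fold change of each fixed gene list in females (red) and males (blue), with the number of tested genes in brackets. Filled points are the 3 lists in females and 1 in males that camera called with its preset correlation; 0 were called with an estimated correlation.

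Whether the sexes shared their changes was asked next. Of the genes called in each sex, 561 rose in both and 802 fell in both, against 87.1 and 123.3 if the calls were independent. The 1363 genes with the same direction stood against 1 with opposite directions, Mpp4, which rose by 3.77 ± 0.85 in females (adjusted p = 0.00526) and fell by 1.73 ± 0.55 in males on the log2 scale (adjusted p = 0.0456) and was singled out after its values were seen. Among genes called in females 94.7% had the same sign in males, and among those called in males 96.8% had the same sign in females. Across genes, which are not independent replicates, the log2 changes of the sexes correlated with a Pearson coefficient of 0.41 and a Spearman coefficient of 0.56.

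**Figure D4:**
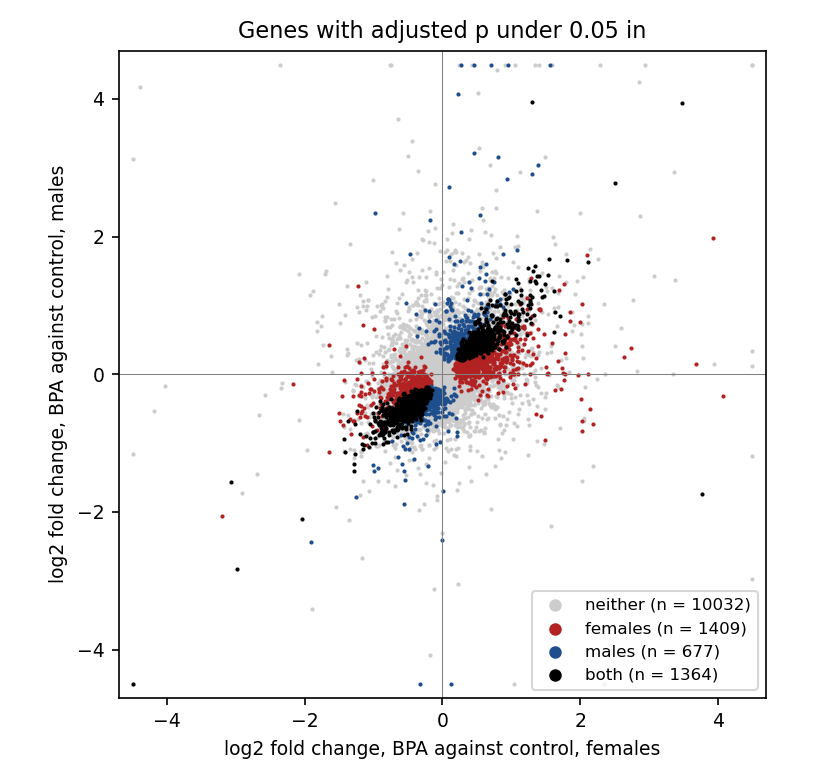
Each point is a tested gene, with its log2 fold change in females on the x axis and in males on the y axis; 30 genes beyond 4.5 on either axis are drawn at the edge. Genes passing in both sexes (1364) lie almost all in the lower left and upper right.

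Averaged over both sexes, 22 of 32 respiratory chain genes rose, 4 fell and 6 did not pass, or 22 and 5 when adjusted over the list alone. Cox5a rose by 0.73 ± 0.05, Ndufa4 by 0.63 ± 0.04, Cox7c by 0.62 ± 0.05 and Ndufa2 by 0.88 ± 0.08, each in 8 of 8 exposed libraries (adjusted p = 1.58e-07, 1.41e-07, 2.63e-07 and 1.17e-06). Camera called the list higher (median 0.21, adjusted p = 1.09e-05), with adjusted p = 0.970 with an estimated correlation and 0.00345 by fry. Gm20594 rose by 3.71 ± 0.16 (adjusted p = 1.28e-09, 8 of 8), Zfp281 by 2.64 ± 0.57 (8 of 8), Rslcan18 by 2.95 ± 0.66 (7 of 8) and Saa2 by 2.92 ± 0.81 (8 of 8, of which 4 lay above all controls). Gm12669 fell by 2.91 ± 0.42 on the log2 scale and Hbb-bt by 7.37 ± 0.74, both in 8 of 8.

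Of 9 blood cell markers, 1 rose and 1 fell on average, by either adjustment. While Hbb-bt fell, the beta globin entry Hbb-b2 rose by 0.90 ± 0.28 (adjusted p = 0.0268, 7 of 8 libraries) and Hbb-bs measured 3.55 ± 1.71 (adjusted p = 0.138), but 0.417 without female BPA 14 and 0.468 without male BPA 4. Hbb-bt shares 59.3% of its sequence with other genes. Reads assigned to one globin entry rather than another can therefore not be told apart from changes of the genes. The erythropoietin receptor gene Epor measured 0.39 ± 0.41 (adjusted p = 0.497), and 0.078 without male BPA 4. Camera did not call the list (adjusted p = 0.904), whose median of 0.02 and mean of −0.27 differed in sign. None of the Kupffer cell, lymphocyte, neutrophil, cholangiocyte or adipose tissue markers passed in either sex, of 16, 15, 3, 10 and 6 tested. Of 15 endothelial markers 1 rose in each sex, by either adjustment, and of 19 stellate cell and fibrosis genes 1 rose in females and none in males, or 0 in each when adjusted over the list alone. The call of Hbb-b2 ended when male BPA 12 and female control 17 were left out together (adjusted p = 0.0595).

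Further genes named by the average were present in part of the libraries. Amd2, a copy of the S-adenosylmethionine decarboxylase gene with 90.9% shared sequence, was at 0 in all 8 controls and present in 5 of 8 exposed libraries, with means of 14.5 ± 9.74 CPM in females and 7.70 ± 9.23 in males (adjusted p = 0.0343). Gm14434, whose sequence is wholly shared, was at 0 in all 8 exposed libraries and at 1.91 ± 3.81 and 5.34 ± 3.59 CPM in female and male controls (adjusted p = 0.0370). Kctd12 was lower in 6 of 8 (adjusted p = 0.0276), and Snurf, which lies wholly within the imprinted gene Snrpn, fell by 2.65 ± 0.85 in 8 of 8 (adjusted p = 0.0295). Of 16 fits with 1 library left out, 5 ended the call of Amd2 (highest adjusted p = 0.0623, without female BPA 8), 9 that of Gm14434 (1, without female control 4) and 7 that of Snurf (0.0972, without male control 7).

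Across all genes, edgeR called 1997 up and 2162 down on average, 30.8% of those tested, with a median absolute log2 change of 0.37. Rises outnumbered falls in other settings, such as upper quartile scaling (2194 and 2041), no expression filter (2101 and 1863), DESeq2 (2375 and 2244) and leaving out male BPA 12 (2241 and 2028). All 8 exposed libraries lay above or below all 8 controls for 863 genes, or 6.4%, where chance gives 0.0155%. With limma-voom, Amd2 (adjusted p = 0.491), Rslcan18 (0.0817), Saa2 (0.304), Gm14434 (0.249) and Snurf (0.610) did not pass.

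Whether the response to BPA differed between the sexes was tested as the male minus the female effect, and no single gene passed. edgeR called 0 genes, with 1019 at an unadjusted p under 0.05, where 674 are due to chance, and a smallest adjusted p of 0.253, whereas DESeq2 called 38 and limma-voom 1. In simulated data of the female comparison, 24 of 146 DESeq2 calls were false, against 4 of 114 with edgeR, and the 38 include Kctd12 with a fitted log2 value of −26.05. DESeq2 was not run on simulated data of the difference, and the simulated spread was estimated with edgeR. The simulation therefore gives no share of false calls among the 38. The genes of lowest p included Gsta2 (−2.04 ± 0.42, adjusted p = 0.419) and Ces1b (−0.57 ± 0.11, adjusted p = 0.332), detoxifying enzymes with a lower measured BPA effect in males, and Gstm4, another glutathione transferase (0.81 ± 0.19, adjusted p = 0.493). Ehd4, of endocytic recycling, measured 0.68 ± 0.12 and the Mediator gene Med12l 1.56 ± 0.29 (adjusted p = 0.253 each). The scramblase gene Plscr1 measured 0.94 ± 0.20, the histone gene H3f3b 0.71 ± 0.16, the polymerase I factor gene Taf1c −1.85 ± 0.39, the histone methyltransferase gene Setdb1 −0.36 ± 0.08 and Ccdc117 −1.02 ± 0.24. These 10 genes passed with DESeq2, with Med12l at adjusted p = 0.00206 and Ehd4 and Gsta2 at 0.00304.

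Gene lists did differ by camera's preset, 6 higher and 6 lower in males of 35, and 0 with an estimated correlation or by fry's test of a common direction. Fry's test of changes in either direction passed for lipoprotein genes (adjusted p = 0.00593). Of these 23 genes, 2 were lower in males when adjusted over the list alone and 0 over all genes. Xenobiotic genes had a median male minus female effect of −0.47 (adjusted p = 1.52e-09, and adjusted p = 0.587 with an estimated correlation), with 4 of 34 lower when adjusted over the list alone and 0 over all genes. Cyp3a11, the main drug-oxidising P450 gene, measured −0.95 ± 0.26, Gsta1 −1.94 ± 0.58 and the glucuronosyltransferase gene Ugt2b36 −0.51 ± 0.16 (adjusted p = 0.498, 0.507 and 0.511). Acute phase genes had a median of 0.35 (adjusted p = 1.09e-05, and 0.587 with an estimated correlation), with 0 of 24 passing by either adjustment. Mt1 measured 2.03 ± 0.63, Mt2 3.09 ± 0.97, the siderophore binder gene Lcn2 3.84 ± 1.23 and Hamp −1.33 ± 0.47 (adjusted p = 0.527, 0.529, 0.529 and 0.562). Heat shock genes had a median of −0.33 (adjusted p = 0.00424, and 0.587 with an estimated correlation), with 4 of 14 lower when adjusted over the list alone. Among these, Dnajb1 measured −1.27 ± 0.31, Bag3 −1.11 ± 0.32, Hspa1a −2.85 ± 0.81 and Hspa1b −2.91 ± 0.83 (adjusted p = 0.493 for Dnajb1 and 0.498 for each other). Fatty acid oxidation genes had a median of 0.18 (adjusted p = 0.00424, and 0.587 with an estimated correlation), with 0 of 31 passing by either adjustment. Ehhadh, of peroxisomal oxidation, measured 0.69 ± 0.28, Acadl 0.24 ± 0.12, Vnn1 0.49 ± 0.26 and Hadha 0.21 ± 0.11 (adjusted p = 0.605, 0.693, 0.715 and 0.718). The heat shock call ended without male control 7 (adjusted p = 0.0567) and the fatty acid oxidation call without female BPA 1 (adjusted p = 0.176).

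The sex difference in control animals was measured as background. Of 20 genes listed as male-biased in liver, 18 were higher in males and 2 did not pass, or 19 when adjusted over the list alone. Of 32 listed as female-biased, 26 were higher in females, or 28 over the list alone. Camera called both lists with the preset (adjusted p = 2.07e-22 and 1.31e-31) and with an estimated correlation (adjusted p = 0.00324 and 6.45e-05). The P450 gene Cyp2d9 was at 1039 ± 137 CPM in males and 53.0 ± 6.73 in females (SD, n = 4; 4.29 ± 0.23, adjusted p = 1.36e-08), the complement gene C6 at 148 ± 25.4 and 17.3 ± 2.61 CPM, Cyp4a12b at 132 ± 30.8 and 0.591 ± 0.743 CPM, and Susd4, a complement regulator gene, at 16.4 ± 3.05 and 1.37 ± 0.154 CPM. Cyp2c69 and Cyp2c40 were lower in males (−4.06 ± 0.19 and −2.51 ± 0.14 on the log2 scale). The sulfotransferase gene Sult2a2 reached 86.4 ± 29.1 CPM in females against 0.0782 ± 0.156 in males. Sequence shared with other genes made up 45.1% of Cyp2d9, 62.4% of Cyp4a12b, 64.8% of Cyp2c69, 83.7% of Cyp2c40 and 73.4% of Sult2a2.

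Genes at 0 in all libraries of a sex gave nominal lower bounds. In control males the Y-linked genes Eif2s3y and Uty were at least 2330-fold and 1150-fold higher, and Ddx3y and the histone demethylase gene Kdm5d were higher by 9.60 ± 0.63 and 8.29 ± 0.48 on the log2 scale, with both at 0 in every control female but control 17. Mup8, a major urinary protein gene with 93.2% shared sequence, was higher by 9.43 ± 1.65. In control females Sult2a1, Sult3a1, Mup17, Cyp3a41b and A1bg were at least 4740-fold, 3630-fold, 3050-fold, 1570-fold and 627-fold higher, of which Sult2a1, Mup17 and Cyp3a41b share 55%, 85.6% and 95.6% of their sequence and Mup17 and Cyp3a41b spanned 47 to 165 and 10.5 to 112 CPM. Xist was at 711 ± 154 CPM in control females and 1.34 ± 0.406 in control males. Esr1 was lower in males (−0.60 ± 0.15, adjusted p = 0.0117), and Esrrg measured −1.12 ± 0.38 (adjusted p = 0.0567). With limma-voom, Mup8 (adjusted p = 0.188), Mup17 (0.0551), Cyp3a41b (0.118) and A1bg (0.0826) did not pass.

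Other lists differed between control sexes with the preset. Of 34 xenobiotic genes, 23 were higher and 2 lower in males, or 25 and 4 over the list alone, such as Cyp3a11 (1.74 ± 0.19), Ugt2b35 (1.12 ± 0.13) and Ces2a (0.96 ± 0.11), with Abcb1a lower (−1.65 ± 0.16). The list was called at adjusted p = 1.57e-08, with adjusted p = 0.294 with an estimated correlation. Interferon genes were lower in males in 7 of 30, or 10 over the list alone, among them Gbp3 (−1.34 ± 0.31), Ifi44 (−1.20 ± 0.29), Oasl2 (−0.89 ± 0.22) and Ddx58 (−0.59 ± 0.15), with adjusted p = 3.29e-06 and adjusted p = 0.507 with an estimated correlation. Stellate cell and fibrosis genes were lower in 10 of 19, or 13 over the list alone, with adjusted p = 3.29e-06 and adjusted p = 0.342 with an estimated correlation. The matrix genes Dcn (−0.47 ± 0.09), Ecm1 (−0.52 ± 0.12), Lum (−0.93 ± 0.24) and the collectin gene Colec11 (−0.47 ± 0.13) were examples, each in 4 of 4 libraries as for all genes of this comparison. The call of Colec11 ended in 2 of 8 fits with 1 library left out (highest adjusted p = 0.0578, without male control 7) and that of Lum with limma-voom (adjusted p = 0.0582), and Lum measured −0.57 without female control 17.

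In exposed animals the same lists separated the sexes. Male-biased genes were higher in males in 18 of 20, or 19 over the list alone, and female-biased genes lower in 25 of 32, or 29 over the list alone (adjusted p = 1.67e-30 and 7.01e-39, and 8.11e-04 and 2.14e-05 with an estimated correlation). Cyp2d9 was higher in males by 4.44 ± 0.23, C6 by 3.44 ± 0.20, Susd4 by 3.45 ± 0.26 and Cyp4a12b by 10.08 ± 0.56. Cyp2c40, Cyp2c69, Sult2a2 and the transporter gene Slc22a26 measured −2.60 ± 0.14, −3.65 ± 0.19, −10.47 ± 0.51 and −7.05 ± 0.45. Eif2s3y, Uty and Kdm5d were at least 2190-fold, 1490-fold and 955-fold higher in exposed males, Scara5, a scavenger receptor gene, was at 9.35 ± 11.4 CPM in exposed males (0.227 to 24.5, the highest in male BPA 12) and at 0 in exposed females, and Ddx3y was higher by 11.74 ± 0.73. Mup17, Cyp3a41b, Sult2a5, Kctd12 and the oxidase gene Hao2 were at least 8330-fold, 1140-fold, 747-fold, 624-fold and 496-fold higher in exposed females, although no male library lay below every female one for Kctd12. Values in exposed females spanned 42.3 to 359 CPM for Mup17, 18.1 to 48.7 for Cyp3a41b, 0 to 37.8 for Kctd12 and 6.08 to 29.8 for Hao2. Xist was at 552 ± 114 CPM in exposed females and 0.721 ± 0.100 in exposed males, and Esr1 was lower in males (−0.66 ± 0.15, adjusted p = 0.00986), with Esrrg at −1.12 ± 0.38 (adjusted p = 0.0820). The call of Kctd12 ended in 6 of 8 fits with 1 library left out (adjusted p = 0.0805 to 0.0958, the highest without female BPA 1), and Esrrg passed without that library (adjusted p = 0.00221). Scara5 and Cyp3a41b did not pass with limma-voom (adjusted p = 0.133 and 0.0970).

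Across all genes, edgeR called 1411 higher and 976 lower in control males than in control females, and 747 higher and 504 lower in exposed males than in exposed females. With upper quartile scaling, which moved the median of all genes to −0.073 and −0.071, the splits were 806 and 1350 in controls and 500 and 711 in exposed animals. The count in controls fell from 2387 to 1489 without male control 7, and that in exposed animals from 1251 to 819 without male BPA 3.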

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

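The tests of gene length and GC content and of sequence shared between gene copies were chosen after the results they measure were seen, and thinning, the comparison by shared sequence or overlap, and the splits of the count difference were added after the data were seen.

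The BPA-associated changes shared by both sexes came with deeper libraries in exposed animals. After every library was thinned to the smallest total, 94% of the genes called on average were called in the same direction, and after a correction for exon length and GC content 82.2% were. Genes with little shared sequence or overlap were called at 85.5% of the rate of other genes (30.2% against 35.3%). Neither shared reads nor length and GC content, as far as the correction removed their effect, explain the changes as a whole. Thinning shows only that unequal precision of the counts does not, since the model already scaled libraries by size. It cannot undo effects of depth on steps before the counts, or a run difference behind the depth, so these stay open. Other splits of the libraries gave at most 3 genes in females, 2 in males and 1195 on average against 2773, 2041 and 4159 for the real split. The real split alone gave as many genes, 1 of 35 in each sex and 1 of 100 on average. No smaller share was possible with these numbers of splits. The splits also treat the animals as exchangeable, which shared litters would break. An effect of BPA, litter, and any handling or batch shared by exposed animals stay open, since the labels give neither litter nor batch and these cannot be told apart from the exposure.

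Counts of 108 genes (0.8% of those tested) switched 10-fold or more between animals of a group. Genes with at least 20% of their sequence shared with another gene were 6 times as frequent among them as among all other genes reaching 10 CPM (53.9% against 9%, ratio interval 4.91 to 7.09, Fisher's exact p = 4.88e-30). Those other genes were not matched to the switching genes by level. The interval covers the draw of switching genes only, and Fisher's test treats gene copies as independent. Assignment of reads among gene copies is therefore a candidate explanation for part of these switches, such as that of Amd2. Genes with exon overlap were 2.81 times as frequent (17.6% against 6.3%, interval 1.72 to 4.07), which lies between what overlap as a cause and its absence would give, so overlap cannot be told apart from other causes. Of the 102 such genes with both values, 37 had neither property, Zfp281 among them, and no biological explanation was tested.

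Fewer genes differed between the sexes in exposed animals (1251) than in controls (2387), a gap that was smaller with limma-voom (1768 against 2218) and DESeq2 (1935 against 2846). An exposed library that stands apart cannot be told apart from other causes. The highest count with 1 exposed library left out was 1156, under the bound of 1591 set beforehand, but that bound was wrong, because leaving out any library of either group lowered its count (controls to between 1489 and 2001), and limma-voom with sample quality weights exceeded the bound. A smaller sex difference in exposed animals stays open: its median change over 3918 sex-differing genes was −0.068, and 11 of 100 splits, the real one included, lay as low, with all splits but the real one between −0.098 and 0.069. The bound set beforehand for this, that more than 5 splits as low would argue against it, was met, but it was also wrong because a value inside the range of the other splits excludes neither a smaller difference nor its absence. The difference between the counts, −1136, was reached by 4 of 100 splits, the real one included, and 2 of these (−1150 and −1234) exchanged a single exposed library. An effect of exposure on the sex difference may be one reason among others that were not tested.

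For the sex differences the real split was again the only 1 of 35 with as many genes. Other splits gave at most 6 genes in controls against 2387 and at most 93 in exposed animals against 1251. For genes whose response differed between the sexes the splits say nothing about chance, since the real count was 0 and all 100 splits gave at least that by construction. The highest of the other splits gave 712. It kept the exposed males together and set female BPA 14 with female controls 18, 1 and 4 against the rest, so the structure of the samples that it points to includes the exposure itself, nearly reversed in females. Chance cannot be excluded for the number of gene lists. With the real split included, in females 32 of 35 splits gave as many lists (3 against at most 16), in males 35 of 35 (1 against at most 13), and for the difference between the sexes 11 of 100 (12 against at most 15).

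These 12 lists had a response to BPA that differed between the sexes by camera's preset, none of them with an estimated correlation. The effect was lower in males for xenobiotic metabolism (adjusted p = 1.52e-09), the respiratory chain (1.00e-06), heat shock (0.00424), amino acid and one-carbon metabolism (0.00631), NRF2 targets (0.0168) and periportal hepatocyte genes (0.0377). It was higher in males for the acute phase (1.09e-05), fatty acid oxidation (0.00424), the interferon response (0.0168), the cell cycle (0.0260), neutrophil markers (0.0383, 3 genes) and cholangiocyte markers (0.0383). The adjusted p with an estimated correlation was 0.587 for all but the interferon response (0.849). Of 16 fits with 1 library left out, the cell cycle and neutrophil lists were called in 6 each, periportal genes in 7, the interferon response in 10, cholangiocyte markers in 13, NRF2 targets in 14, amino acid metabolism, heat shock and fatty acid oxidation in 15 each and the other 3 in 16. Of the other alternatives, cholangiocyte markers were called in 1 of 6 and neutrophil markers in 1 of 5, the cell cycle and NRF2 targets in 4 of 6, and the rest in 5 of 6. The highest adjusted p was 0.245 for the cell cycle (without male control 2), 0.151 for neutrophil markers and 0.0749 for amino acid metabolism (without male BPA 15), 0.122 for periportal genes (without male BPA 3), 0.455 for the interferon response and 0.199 for NRF2 targets (without male control 7), and 0.134 for cholangiocyte markers (without female BPA 8).

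Of 264 group values examined, 27 had a sample far from the other 3 of its group. Chance marks about 1 in 20 groups, or 13, if values are normally distributed. Most values were of genes named for their changes in these data, and any count is marked where the other 3 libraries stand at 0. The number marked can therefore not be read against 13. Among female controls, Utp14b was at 9.18 CPM in control 1 (others 0.435 to 0.697) and Med12l at 10.7 CPM (15.5 to 16.3). In female control 4 Stx16 was at 23.1 CPM (4.8 to 6.45) and Gm14434 at 7.63 CPM (others 0), and in female control 18 Phtf1os was at 5.07 CPM (0.699 to 0.967). Female control 17 had Snurf at 0 CPM (5.78 to 6.63) and Ddx3y, Kdm5d and Scara5 at 0.967, 0.338 and 0.435 CPM (others 0). Its Ddx3y and Kdm5d values rest on 20 and 7 counts.

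Female BPA 1 had 15701 genes with a count (others 15366 to 15414), Hbb-bt at 0.492 CPM (others 0) and Esrrg at 2.61 CPM (11.6 to 12.5). Female BPA 14 had Tcf20 at 102 CPM (117 to 119) and Amd2 at 0 CPM (17.7 to 20.5), and female BPA 9 had Ddx3y at 0.148 CPM (others 0).

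Male control 2 had a total of 21.1 M counts (23.4 to 23.6), Ly6e at 14.0 CPM (6.75 to 7.33) and Hao2 at 0.151 CPM (others 0). Male control 3 had Fam134c at 14.9 CPM (64.4 to 68.3). Male control 7 had Zfp281 at 22.7 CPM (3.85 to 4.47) and Gm14434 at 0 CPM (6.65 to 7.74). Male control 10 had Sco2 at 10.5 CPM (0.654 to 2.14) and Ephb6 at 0.0894 CPM (others 0). Male BPA 12 had Zfp281 at 79.7 CPM (51.6 to 54.9) and Tcf20 at 128 CPM (111 to 113). Male BPA 15 had Rsc1a1 at 2.42 CPM (14.2 to 15.8) and Snurf at 0.298 CPM (0 to 0.0379).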

How the results depend on the processing

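Thinning to equal depth, the length and GC correction, leaving out switching genes, genes with shared sequence or overlap, or male BPA 12 with female control 17, and all alternatives for the genes changed in the same direction in both sexes were chosen after seeing the data; the others were planned. Which direction had more genes turned with some settings for each comparison with BPA, and with upper quartile scaling for both comparisons of the sexes. Of the named genes, Uty in males turned from −0.07 to 0.044 with the length and GC correction (adjusted p = 0.812), without passing in either, and no other reversed its direction. Genes changed by BPA in females numbered 2773, with 2122 to 2514 when 1 library was left out and 2250 to 3264 under the other alternatives. In males these were 2041, 1467 to 1841 and 1643 to 2560, on average 4159, 3779 to 4269 and 3425 to 4738, and for the same direction in both sexes 1363, 1020 to 1361 and 984 to 1728. The sex difference in controls gave 2387 genes, 1489 to 2001 and 1762 to 2846, and in exposed animals 1251, 819 to 1156 and 907 to 1935, the last with DESeq2. No gene differed in its response between the sexes with edgeR, whereas DESeq2 gave 38 genes (1147 at an unadjusted p under 0.05). limma-voom gave 1 (Utp14b, 1056 unadjusted), and leaving out male BPA 12 with female control 17 gave 1 (Snrpn). Leaving out 1 library gave 0 to 1, with Snrpn without female control 17, Morf4l2 without female control 18, Utp14b without female control 1 and Jund without male control 10, all named after their values were seen. Lists changed in females numbered 3, with 3 to 4 when 1 library was left out, in males 1 with 1 to 3 (beside the calls given for heat shock and the acute phase, the interferon response without male BPA 12, cholesterol synthesis without male BPA 15 and ribosomal proteins without male BPA 15 or male control 7), and for the difference between the sexes 12 with 6 (without male control 7) to 15, and 7 without male BPA 15. With an estimated correlation all these became 0, and without male BPA 12 and female control 17 the lists in males became 3. For the difference, some alternatives also called Kupffer cell, blood cell and endothelial markers and male-biased liver genes, with a higher effect in males. Others called sex chromosome, cholesterol synthesis, bile acid and ribosomal protein genes, with a lower effect in males. Apart from fewer samples in fits with libraries left out, the cause was not tested.

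Of the named genes called, 41 of 55 in females, 21 of 42 in males, 8 of 15 on average, 26 of 32 for the sexes in controls and 17 of 20 in exposed animals kept their call and direction under every alternative that gave them an adjusted p. An alternative that dropped a gene was not counted against it. Single genes were not followed when switching genes or genes with shared sequence or overlap were left out. Each gene under each alternative kept its side of the threshold 1047 times in females and 751 in males, and lost its call 83 and 138 times. Most of these losses came with 1 library left out. No paired analysis was possible because the compared groups share at most 1 sample number. Depth limits genes with few counts: a group at 0 in all libraries allows up to 0.0229 CPM in exposed females, 0.0314 in control females, 0.029 in exposed males and 0.0349 in control males, for counting error only.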

Other observations

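Of 22 enzymes of DNA methylation and chromatin, 4 fell, none rose and 18 did not pass in exposed females, by either adjustment, where 20.6% of all tested genes passed. The histone deacetylase genes Hdac2 and Hdac1 fell by 0.35 ± 0.08 and 0.26 ± 0.07 on the log2 scale, Tet2, which oxidises methylcytosine, by 0.53 ± 0.13, and Eed, of the Polycomb repressive complex, by 0.34 ± 0.09 (SE, n = 4; edgeR adjusted p = 0.00699, 0.0192, 0.00888 and 0.0101, each in 4 of 4 libraries). Hdac1 shares 62.7% of its sequence, and its call ended without female control 18 (adjusted p = 0.0524). Neither camera (adjusted p = 0.266) nor fry's test of a common direction (0.0952) called the list, whereas fry's test of changes in either direction passed (adjusted p = 1.38e-06). In males 1 of the 22 fell. Of 23 lipoprotein genes, 5 rose and 2 fell in females by either adjustment. Apoc3, the triglyceride-raising apolipoprotein gene, went from 550 ± 32.6 to 810 ± 108 CPM (0.56 ± 0.09, adjusted p = 3.02e-04), Apom rose by 0.48 ± 0.08, Apoc4 by 0.44 ± 0.09 and Apoh by 0.26 ± 0.07, each in 4 of 4 libraries, and the list was not called (adjusted p = 0.603). The call of Apoh ended without female control 17 (adjusted p = 0.0549).

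Short non-coding RNA genes, grouped by type after the values were seen, had positive medians in both sexes. The 19 tested snoRNA genes had a median log2 change of 0.55 in females and 0.75 in males, with 4 and 7 up, 1 and 1 down and 3 up in both sexes. The 13 miRNA genes had medians of 0.55 and 0.59, and the 4 scaRNA genes 0.69 and 0.60. The 12773 protein-coding genes had medians of 0.01 and 0.00. Of 25 cholesterol synthesis genes, none passed in females, and in males 2 fell, or 1 when adjusted over the list alone. Of 23 fatty acid and triglyceride synthesis genes, 2 rose and 2 fell in females (2 and 1 when adjusted over the list alone), and 1 rose and 1 fell in males by either adjustment. Of 20 clock genes, 2 rose in each sex (0 in females and 2 in males when adjusted over the list alone). Of 23 bile acid genes, 4 rose and 1 fell in females by either adjustment, and 2 rose in males (0 when adjusted over the list alone). Camera called none of these 4 lists in either sex (smallest adjusted p = 0.317), apart from cholesterol synthesis, lower in males without male BPA 15 (0.0494).

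Across genes, in a comparison also chosen after the values were seen, log2 changes had Spearman coefficients of 0.20 and 0.22 with GC content and −0.09 and −0.07 with exon length in females and males, over 13346 genes that are not independent replicates.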
